A study of Canis lupus familiaris with 6 samples.

How the data were processed

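The series holds 6 single-colour Affymetrix gene expression arrays of total RNA from MDCK cells, an epithelial line from dog kidney (Madin-Darby canine kidney) that forms polarised sheets joined by tight junctions and E-cadherin. Per the labels, 2 arrays came from untreated cells and 2 from cells kept for 30 days in transforming growth factor beta (TGFb, 5 ng/ml) with regular subculture. A single array came from TGFb-treated cells given 5-AZA for 72 hours, and the labels do not say whether TGFb was kept during that time. Another came from cells 30 days after TGFb was withdrawn. The labels do not say whether the arrays of a group came from separate cultures. All p-values therefore measure the spread between these samples, which may be technical.

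The deposited table gives one value per probe set and array on a log scale. Per the submitters' processing notes the values were made with Affymetrix Expression Console 1.2, and the summary method, the background correction and the base of the logarithm are not given in the sources used here. The values run from 0.937 to 13.1 with array medians between 4.97 and 5.01, the range of log2 values from a 16-bit scanner, so the deposited values were read as log2. Had another base been used, the listed differences would be multiplied by a constant, and the adjusted p-values would stay as they are. Values were not centred per gene. No background level is given, so the limit of detection of each array is unknown, and the number of arrays limits the precision.

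The table holds 32293 probe sets. The platform annotation gives 1 gene symbol for 16545 of them, several for 370 and none for 15378, and no gene was named from a probe set with several. The entrez identifiers of 15820 probe sets were found in the RefSeq gene table of assembly UU_Cfam_GSD_1.0, which was used for current symbols and for gene order. No coordinate is given, as the build behind the array is not named. For 516 genes with more than 1 probe set of their own, the one with the highest mean over the 6 arrays stood for the gene, which left 15947 genes. Another 1573 probe sets carried values identical on all 6 arrays to those of an earlier one. Among the probe sets with 1 symbol 7 repeated another of that kind. A probe set that matches near-identical family members cannot separate them.

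Group means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without an intensity trend and not robust). Benjamini-Hochberg adjusted p-values under 0.05 over all 32293 probe sets were called, with no filter on low signals. The 2 residual degrees of freedom came from the untreated and TGFb arrays, and moderation added 3.10 prior degrees of freedom. The single 5-AZA and withdrawal arrays were assumed to vary like the replicated groups, an assumption these data cannot check. Errors after ± on log2 differences are standard errors of the fit. The comparisons were TGFb against untreated, withdrawal against TGFb and untreated, and 5-AZA against TGFb and untreated.

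Before the data were examined, 20 gene lists holding 500 symbols were fixed. They covered epithelial junctions and polarity, epithelial identity, EMT transcription factors, mesenchymal cytoskeleton and adhesion, extracellular matrix, matrix proteases and inhibitors, TGFb signalling, integrins and laminins, and kidney tubule transport. The others were cell cycle, p53 targets and CDK inhibitors, DNA methylation machinery, germline genes, interferon response, inflammatory mediators, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid response, leukocyte, endothelial and neuronal markers, and housekeeping genes. Of these symbols 51 had no probe set of their own, among them the anchor TWIST1. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison. A second run estimated the correlation from the 2 residual degrees of freedom, and its test has only those 2 degrees of freedom. At the preset 0.01, 46 list tests passed over the 5 comparisons, and none of them passed with an estimated correlation. Epithelial identity under TGFb had an estimated correlation of −0.023, below the preset, yet its unadjusted camera p went from 1.47e-22 to 0.00832. A call lost in the second run therefore does not by itself show that correlation between genes undid it. Other lists had estimates far above the preset, among them interferon response (0.374), hypoxia and glycolysis (0.218) and EMT transcription factors (0.137). For such lists correlation may have undone the call, and the second run cannot separate this from its few degrees of freedom. The preset itself was not tested. Members are counted with p-values adjusted over all probe sets, named or not, which the text calls over all genes tested. In a second count they are adjusted over the list alone.

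Named genes followed a rule fixed at the same time. It took the 10 largest called changes each way for TGFb against untreated and 6 each way for the single-array comparisons, where every array of one group lay above every array of the other. Where nothing was called, the 5 largest differences each way are given as values. It also took anchor genes of the epithelial-mesenchymal transition (EMT), which are CDH1, EPCAM, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2, TWIST1 and DNMT1, and up to 4 members per list with the smallest adjusted p. Other genes named were chosen after their values were seen. The text says so for the genes under other observations. Further list members in the Results were also chosen that way. Among them, for 5-AZA against TGFb, are some of the 9 germline genes called, and ACTA2 and TAGLN. Another anchor is not reported here.

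The return of TGFb-called probe sets was described as the share nearer to the untreated than to the TGFb mean, with exact Clopper-Pearson 95% intervals. These intervals treat probe sets as independent, which they are not. Because the same arrays chose and measured these probe sets, the share was also computed with separate arrays. There 1 array pair picked the same number of probe sets by largest difference, called or not, and the other pair measured the distance.

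The scripts were tested on simulated data built from the real means, with 200 of 32293 probe sets changed. Variances were drawn at random from the fitted prior, with independent noise and the same variance on every array. The rates below hold under those assumptions. For 2 arrays against 2, 0.448%, 69.4% and 95.9% of log2 changes of 1, 2 and 4 were recovered, and 6.14% of calls were false. For 1 array against 2 untreated arrays the recovered shares were 0%, 31.6% and 90.5%, with 4.71% false calls. Alternatives were an intensity trend, robust moderation, a filter on signal, quantile normalization, median centring, a minimum 2-fold change, averaged probe sets per gene, a replicate block, and leaving out each replicated array. Counting identical rows once and testing only the 15947 named genes were added after the data had been seen. Figures were drawn with matplotlib.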

Results

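Expression was measured in MDCK cells under 4 conditions, with 2 arrays of untreated cells, 2 of cells grown for 30 days with TGFb, 1 of TGFb-treated cells exposed to 5-AZA for 72 hours and 1 of cells 30 days after TGFb withdrawal. TGFb is a growth factor that can drive epithelial cells into a mesenchymal state, and 5-AZA is the usual short name of 5-azacytidine or its deoxy form, which block DNA methylation (the labels do not say which was used). The submitters described the untreated and withdrawn cells as epithelial and the TGFb-treated cells as mesenchymal. Over all probe sets the untreated arrays correlated with each other at r = 0.984 and the TGFb arrays at r = 0.987. Untreated and TGFb arrays correlated at 0.964 to 0.972, and the withdrawal array with the untreated arrays at 0.978 and 0.981. The 5-AZA array stood closer to the TGFb arrays (0.968 and 0.970) than to the withdrawal array (0.947). On the first principal component, which held 46.6% of the variance, the withdrawal array scored −46.3 beside −45.8 and −43.9 for the untreated arrays. The TGFb arrays scored 35.1 and 28.9, and the 5-AZA array 72.0.

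The first comparison asked what 30 days of TGFb changed. CDH1, which encodes E-cadherin, the adhesion molecule of epithelial junctions, fell by 4.79 ± 0.35 on the log2 scale (adjusted p = 0.0113), from 11.53 ± 0.15 to 6.74 ± 0.71 (SD, n = 2 each). The CDH1 repressors ZEB1 (5.00 ± 0.39, adjusted p = 0.0133) and ZEB2 (3.83 ± 0.43, adjusted p = 0.0312) rose. Matrix genes gave several of the largest increases, with LUM, encoding the proteoglycan lumican, at 7.68 ± 0.32 and SPARC, a collagen-binding glycoprotein, at 6.23 ± 0.28. Of 29 genes of the antiviral interferon response 11 fell, among them IFI44L at −5.74 ± 0.22.

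Among 26 measured genes of epithelial junctions and polarity, 12 fell, none rose and 14 did not pass over all genes tested, and 18 fell when adjusted over the list alone (mean log2 difference −1.62, adjusted p = 1.14e-17, and adjusted p = 0.278 with an estimated correlation). The tight junction genes OCLN (log2 difference −4.11 ± 0.26) and CLDN1 (−4.52 ± 0.35), the polarity scaffold PATJ (−3.33 ± 0.21) and EPCAM (−3.32 ± 0.42, adjusted p = 0.0402) were among them. Of 25 epithelial identity genes, 14 fell and none rose over all genes tested, and 20 fell when adjusted over the list alone (mean log2 difference −1.99, adjusted p = 2.94e-21, and adjusted p = 0.166 with an estimated correlation). The transcription factor GRHL2, a known driver of epithelial gene expression, changed by −5.21 ± 0.30, the vesicle trafficking gene RAB25 by −3.71 ± 0.20, MAL2 by −5.62 ± 0.60, and the keratins KRT19 and KRT7 by −5.46 ± 0.31 and −2.92 ± 0.19.

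Of 14 EMT transcription factors, 4 rose and none fell, both over all genes tested and adjusted over the list alone (mean log2 difference 1.10, adjusted p = 0.0239, and adjusted p = 0.563 with an estimated correlation). These were ZEB1, ZEB2, TCF4 (4.96 ± 0.21) and SNAI2 (2.10 ± 0.29, adjusted p = 0.0482). SNAI1 differed by 0.06 ± 0.20 (adjusted p = 0.923), and the list's median was 0.04. The camera call on this list ended without untreated replicate 2 (mean 0.96) and without TGFb replicate 2 (mean 1.09). Of 31 extracellular matrix genes, 7 rose and none fell over all genes tested, and 11 rose when adjusted over the list alone (mean log2 difference 1.22, adjusted p = 2.90e-08, and adjusted p = 0.278 with an estimated correlation). Fibrillar collagens were among them, with COL1A2 at 3.96 ± 0.15 and COL3A1 at 2.76 ± 0.20, as was the proteoglycan gene DCN (4.85 ± 0.42), but FN1, encoding fibronectin, differed by 0.60 ± 0.31 (adjusted p = 0.465). The untreated cells already carried a high FN1 signal of 11.47 ± 0.60 (SD, n = 2).

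Of 22 mesenchymal cytoskeleton and adhesion genes, only 2 rose over all genes tested, CALD1 (3.77 ± 0.45) and CDH2 (1.33 ± 0.18, adjusted p = 0.0472), and PDGFRA fell (−2.58 ± 0.31). Adjusted over the list alone 5 rose and 1 fell (mean log2 difference 0.49, adjusted p = 0.00665, and adjusted p = 0.299 with an estimated correlation). VIM, encoding vimentin, differed by 0.38 ± 0.14 (adjusted p = 0.318) from an untreated signal of 11.89 ± 0.01. Among 19 matrix proteases and inhibitors, the inhibitor TIMP3 fell (−3.18 ± 0.32) and none rose over all genes tested. Adjusted over that list alone 4 rose and 1 fell, and the list as a set lay higher (mean log2 difference 0.32, adjusted p = 0.0223, and adjusted p = 0.299 with an estimated correlation), a call lost with the dimmer probe sets dropped. In the TGFb signalling list (27 measured) BAMBI (5.08 ± 0.18), INHBA and TGFB2 rose and none fell, or 5 and 1 adjusted over the list alone (list adjusted p = 0.14).

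Of 29 interferon response genes, 11 fell and none rose over all genes tested, and 21 fell when adjusted over the list alone (mean log2 difference −1.81, adjusted p = 3.57e-18, and adjusted p = 0.299 with an estimated correlation). OAS2, a sensor of viral RNA, changed by −5.49 ± 0.22, RSAD2 by −5.38 ± 0.51 and USP18 by −3.68 ± 0.18. No cell cycle gene of 33 was called in either count, while 28 lay higher (mean log2 difference 0.33, adjusted p = 2.30e-05, and adjusted p = 0.299 with an estimated correlation). In the hypoxia and glycolysis list (23 measured) CA12 (3.56 ± 0.41) and P4HA1 rose and EGLN3 fell, or 8 and 1 adjusted over the list alone (mean log2 difference 0.33, adjusted p = 0.0223, and adjusted p = 0.57 with an estimated correlation). The camera call on this list ended without untreated replicate 1 (mean 0.28) and without TGFb replicate 1 (mean 0.18). Outside the lists, KERA (7.43 ± 0.18), NEGR1, GPNMB and TNFSF4 were among the 10 largest increases, and SPINK5 (−6.49 ± 0.71), FGFBP1 (−6.35 ± 0.21), RASSF6, SH3YL1, RASEF, ALDH1A1 and PLS1 among the 10 largest decreases.

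The remaining lists did not pass for TGFb against untreated. In integrins and laminins (22 measured, adjusted p = 0.486) LAMA4 rose by 1.99 and ITGB4 and ITGB6 fell, with 3 higher and 6 lower adjusted over the list alone. In kidney tubule transport and identity (35 measured, adjusted p = 0.3) CA2 rose by 1.39 and the transcription factor TFCP2L1 fell by 2.17, with 1 higher and 2 lower over the list alone. A single germline gene of 28, MEIOB (1.25 ± 0.16), rose in both counts (list adjusted p = 0.677), and CSF2 alone fell among 26 inflammatory mediators (−2.35 ± 0.31, list adjusted p = 0.912). Adjusted over that list alone, 1 inflammatory gene was higher and 2 lower. DNMT1, the maintenance DNA methyltransferase, differed by −0.02 ± 0.15 (adjusted p = 0.975), and no DNA methylation gene of 15 was called over all genes tested (2 higher adjusted over the list alone, list adjusted p = 0.486). No member was called in either count among p53 targets and CDK inhibitors (18 measured, list adjusted p = 0.486), cholesterol synthesis (12, 0.53) or the unfolded protein and amino acid response (19, 0.396). The same held for leukocyte, endothelial and neuronal markers (17, 0.483) and housekeeping genes (9, 0.363).

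In all, limma called 531 of 32293 probe sets, 223 higher and 308 lower under TGFb, which took in 158 higher and 234 lower named genes. All 531 separated the 2 TGFb from the 2 untreated arrays, a separation that chance gives a single probe set in 33.3% of cases, and the smallest called log2 difference was 1.01. The count fell to 70 without untreated replicate 1, 129 without untreated replicate 2, 97 without TGFb replicate 2 and 0 without TGFb replicate 1, where 1 residual degree of freedom was left. It was 1001 with the dimmer probe sets dropped and 1228 with only named genes tested. SNAI2 was no longer called under quantile normalization or robust moderation, nor CDH2 and P4HA1 under quantile normalization.

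**Figure D1:**
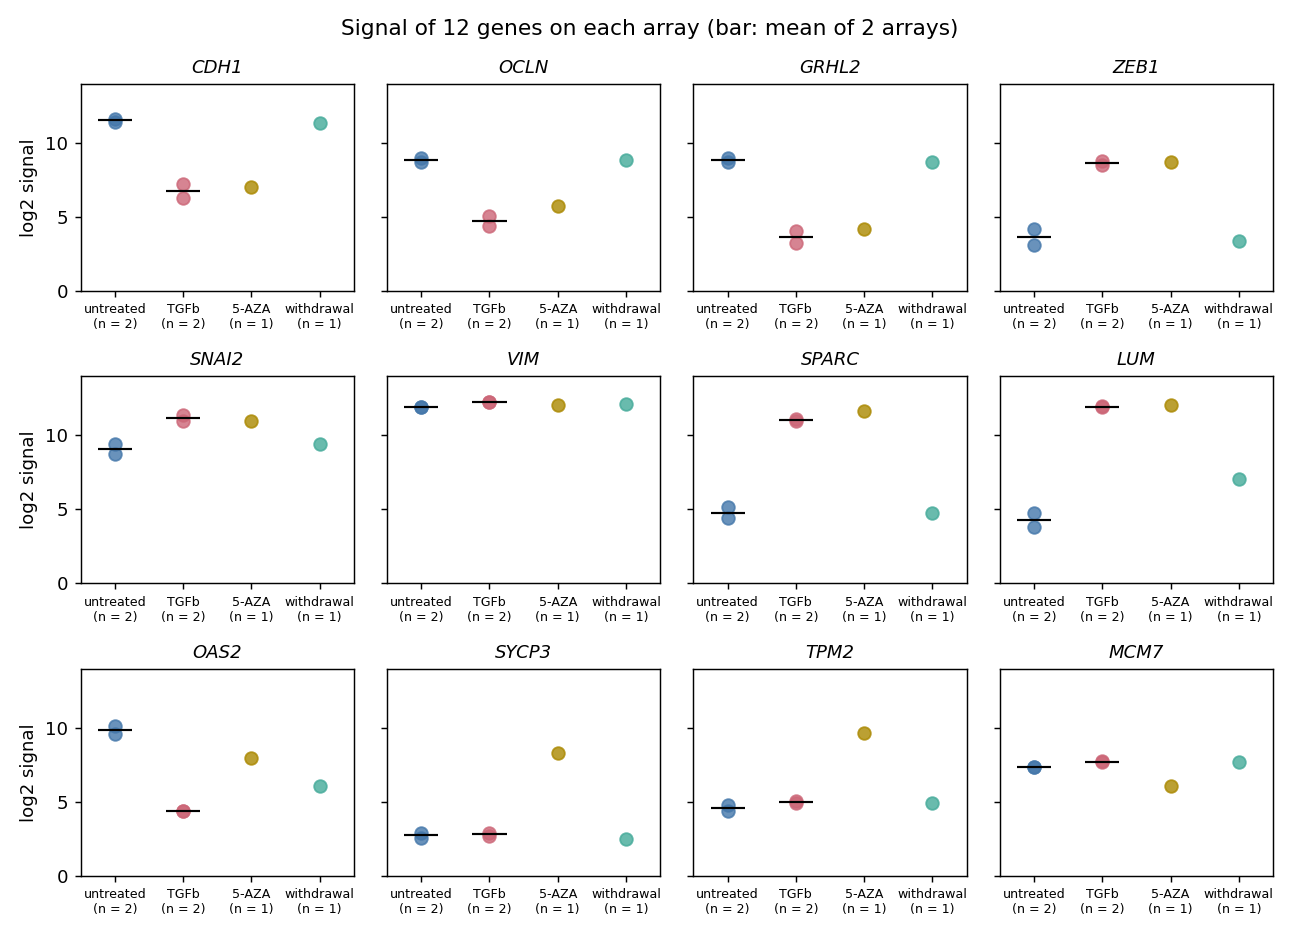
Log2 signal (vertical axis) of 12 genes on each of the 6 arrays, grouped by condition on the horizontal axis, with a point per array and a bar at the mean of 2 arrays. CDH1 stood at 11.53 in untreated cells, 6.74 under TGFb, 6.98 in the 5-AZA array and 11.34 after withdrawal, whereas SYCP3 was high on the 5-AZA array alone (8.27, with 2.75 in untreated cells).

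The withdrawal array addressed whether expression moved when TGFb was removed. Against the TGFb arrays CDH1 rose by 4.60 ± 0.43 (adjusted p = 0.0292), while ZEB1 (−5.26 ± 0.48, adjusted p = 0.0285), ZEB2 (−4.54 ± 0.53, adjusted p = 0.0451) and TCF4 (−4.63 ± 0.26) fell. FGFBP1, encoding a fibroblast growth factor carrier, rose by 8.25 ± 0.26 and the keratin KRT19 by 5.54 ± 0.38. KERA (−6.93 ± 0.23), SPARC (−6.29 ± 0.34), MMP13 (−6.10 ± 0.72, adjusted p = 0.0469), BAMBI, CALD1 and NEGR1 were the largest decreases, and SH3YL1, PLS1, ST8SIA6 and TMEM45B were among the largest increases. The anchors EPCAM (3.36 ± 0.52, adjusted p = 0.0813) and SNAI2 (−1.75 ± 0.36, adjusted p = 0.138) did not pass. Nor did FN1 (−1.79 ± 0.38), CDH2 (−0.77 ± 0.22), VIM (−0.17 ± 0.17), SNAI1 (−0.20 ± 0.25) or DNMT1 (0.39 ± 0.18).

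Of the epithelial junction genes 8 rose and none fell over all genes tested, and 14 rose when adjusted over the list alone (mean log2 difference 1.66, adjusted p = 3.10e-16, and adjusted p = 0.235 with an estimated correlation). CLDN7 (4.24 ± 0.34) and OCLN (4.11 ± 0.31) were among them. Of the epithelial identity genes 6 rose and none fell, including RAB25 (4.97 ± 0.24) and GRHL2 (5.04 ± 0.37), with 19 higher over the list alone (mean log2 difference 2.02, adjusted p = 1.67e-20, and adjusted p = 0.172 with an estimated correlation). Of the EMT transcription factors 3 fell and none rose (4 lower over the list alone; mean log2 difference −1.13, adjusted p = 0.0109, and adjusted p = 0.468 with an estimated correlation). Extracellular matrix genes counted 7 that fell, among them COL1A2 (−4.15 ± 0.19) and LUM (−4.86 ± 0.40), and none that rose, with 12 lower over the list alone (mean log2 difference −1.31, adjusted p = 4.42e-10, and adjusted p = 0.235 with an estimated correlation).

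In the TGFb signalling list BAMBI, LTBP1 (−3.38 ± 0.21), INHBA, TGFB2 and PMEPA1 fell and none rose (1 higher and 6 lower over the list alone; mean log2 difference −0.63, adjusted p = 0.00478, and adjusted p = 0.354 with an estimated correlation). CALD1, CDH6 and the collagen receptor DDR2 fell among mesenchymal genes (1 higher and 3 lower over the list alone; mean log2 difference −0.57, adjusted p = 0.0294, and adjusted p = 0.354 with an estimated correlation). MMP13 alone fell among proteases and inhibitors (2 higher and 6 lower over the list alone; mean log2 difference −0.84, adjusted p = 9.49e-04, and adjusted p = 0.235 with an estimated correlation). IFI44L alone rose among interferon genes (2.68 ± 0.27), with 7 higher over the list alone (mean log2 difference 0.71, adjusted p = 2.81e-05, and adjusted p = 0.536 with an estimated correlation). No unfolded protein response gene was called over all genes tested (3 lower over the list alone; mean log2 difference −0.44, adjusted p = 4.14e-04, and adjusted p = 0.235 with an estimated correlation). The other 11 lists did not pass (adjusted p = 0.175 to 0.987), though NID2 (1.91 ± 0.19), TFCP2L1 (2.68 ± 0.18) and PDK4 (2.21 ± 0.18) rose and ITGB3, LAMA4 and CA12 (−4.37 ± 0.50) fell among their members. Limma called 271 probe sets between withdrawal and TGFb, 119 higher and 152 lower. The count fell to 97 without either untreated array and to 0 without either TGFb array, and was 649 with the dimmer probe sets dropped and 907 with only named genes tested. PLS1, MMP13, ZEB2 and LAMA4 were no longer called under quantile normalization or robust moderation, PLS1 also with median centring, and CA12 under robust moderation.

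Set against untreated cells, the withdrawal array asked what still differed. CDH1 differed by −0.19 ± 0.43 (95% interval −1.28 to 0.90), EPCAM by 0.03 ± 0.52 (−1.29 to 1.36), ZEB1 by −0.26 ± 0.48 (−1.48 to 0.96) and SPARC by −0.06 ± 0.34 (−0.93 to 0.81). The largest positive differences were LUM at 2.82 ± 0.40, adjusted p = 0.282, AREG (2.43 ± 0.62), NID2 (2.37), DHRS9 (2.16 ± 0.38) and TNIK (2.15). The largest negative ones were MMP13 at −5.28 ± 0.72, adjusted p = 0.279, ADGRL2 (−4.23), ADD3 (−4.09), VEGFC (−4.01) and OAS2 (−3.78 ± 0.27, adjusted p = 0.199). AREG read 7.9 and 6.4 on the untreated arrays, so its difference depends on the array taken. LUM and OAS2 had been called under TGFb, but MMP13 (0.82 ± 0.59), ADGRL2 (−1.29 ± 0.28) and ADD3 (−2.11 ± 0.44) had not. Such a difference need not be a remainder of the TGFb change. SNAI2 differed by 0.35 ± 0.36, CDH2 by 0.55 ± 0.22, VIM by 0.20 ± 0.17, FN1 by −1.19 ± 0.38, SNAI1 by −0.13 ± 0.25, ZEB2 by −0.71 ± 0.53 and DNMT1 by 0.37 ± 0.18. None of these differences between withdrawal and untreated passed over all probe sets.

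No member of any list was called when adjusted over all probe sets. In the test of named genes alone, chosen after the data had been seen, some members were called, among them OAS2 and MMP13 lower and LUM higher. Epithelial junction genes had a mean of 0.04 (adjusted p = 0.766) and identity genes 0.03 (adjusted p = 0.988). Of the 29 interferon genes 24 lay lower, 13 of them called when adjusted over the list alone (mean log2 difference −1.09, adjusted p = 7.87e-14, and adjusted p = 0.443 with an estimated correlation). Cell cycle genes lay higher, 30 of 33, with none called over the list alone (mean log2 difference 0.30, adjusted p = 6.68e-05, and adjusted p = 0.443 with an estimated correlation). The unfolded protein response (mean log2 difference −0.35, adjusted p = 9.03e-04, and adjusted p = 0.443 with an estimated correlation), TGFb signalling (mean log2 difference −0.26, adjusted p = 0.00675, and adjusted p = 0.443 with an estimated correlation) and p53 target lists (mean log2 difference −0.30, adjusted p = 0.00873, and adjusted p = 0.443 with an estimated correlation) lay lower. Over the list alone 2 TGFb signalling genes were called lower and none of the other 2 lists. Hypoxia genes lay higher, 1 of them called over the list alone (mean log2 difference 0.24, adjusted p = 0.0425, and adjusted p = 0.786 with an estimated correlation). Without untreated replicate 1 the camera calls on TGFb signalling (mean −0.19), p53 targets (mean −0.22) and hypoxia (mean 0.18) ended, and the hypoxia call also ended under quantile normalization, the signal filter and averaged probe sets. The other 14 lists had adjusted p from 0.0586 to 0.988.

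Limma called none of the 32293 probe sets between withdrawal and untreated, with a smallest adjusted p of 0.199, while 3154 had an unadjusted p under 0.05, 1392 higher and 1762 lower. Differences of at least 2-fold numbered 320 higher and 811 lower. In the simulations of 1 array against 2, 0% and 31.6% of log2 changes of 1 and 2 were recovered. The absence of calls therefore does not show that no difference remained. The intensity trend, robust moderation, quantile normalization, median centring and each left-out array also gave 0 calls, as did dropping the dimmer probe sets (16147 tested) and counting identical rows once. A single setting gave calls: with unnamed probe sets left out and 1 probe set kept per gene, 58 of 15947 genes were called, 9 higher and 49 lower. The settings with identical rows merged and with named genes were chosen after the data had been seen. The latter made both changes together and refitted the moderation on the remaining rows, so no single step can be credited with the 58. MMP13 (adjusted p = 0.0281), OAS2 (0.00727), IFI44L (0.00727), COL12A1 (0.0324), LTBP1 (0.00727) and ALDH1A1 (0.00727) were lower in that test, and LUM (0.0341), NID2 (0.00727) and FGFBP1 (0.036) higher.

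Of the 531 probe sets called under TGFb, 433 (81.5%, interval 78.0 to 84.8) stood nearer to the untreated than to the TGFb mean in the withdrawal array, and 58 (10.9%, 8.40 to 13.9) did in the 5-AZA array. For the higher-called the withdrawal share was 91.0% and for the lower-called 74.7%. The lower-called had a median log2 difference from untreated of −1.98 under TGFb, −0.42 after withdrawal and −1.77 in the 5-AZA array. The higher-called had 1.82, 0.02 and 2.17. Both shares moved with the arrays used. Among the fewer probe sets called without untreated replicate 1 (70), untreated replicate 2 (129) or TGFb replicate 2 (97), the share was 82.9, 76.0 and 90.7% for withdrawal and 2.86, 5.43 and 14.4% for 5-AZA, and without TGFb replicate 1 none were called. In a different set, the 531 probe sets with the largest difference on 1 array pair, distances were measured on the other pair. Of these, 255 to 279 were among the called. Their share was 74.2 to 76.8% for withdrawal and 17.9 to 25.2% for 5-AZA. The change from the shares of the called probe sets may come from the set or from the separate arrays. Calls in opposite directions for TGFb against untreated and withdrawal against TGFb numbered 105 with TGFb high and 98 with TGFb low, where independent lists would share 1.05 and 1.13 and simulated unchanged groups 0.02 on average. The covariance of the log2 differences across probe sets was −0.212 beside a simulated −0.0449. With a different TGFb array in each difference, a check added after the data had been seen, it was −0.171 and −0.179. Part of the overlap of calls may come from the shared TGFb arrays, since calls were not made on separate ones. Groups simulated without change leave few calls to share, so the simulated overlap cannot size that part.

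**Figure D2:**
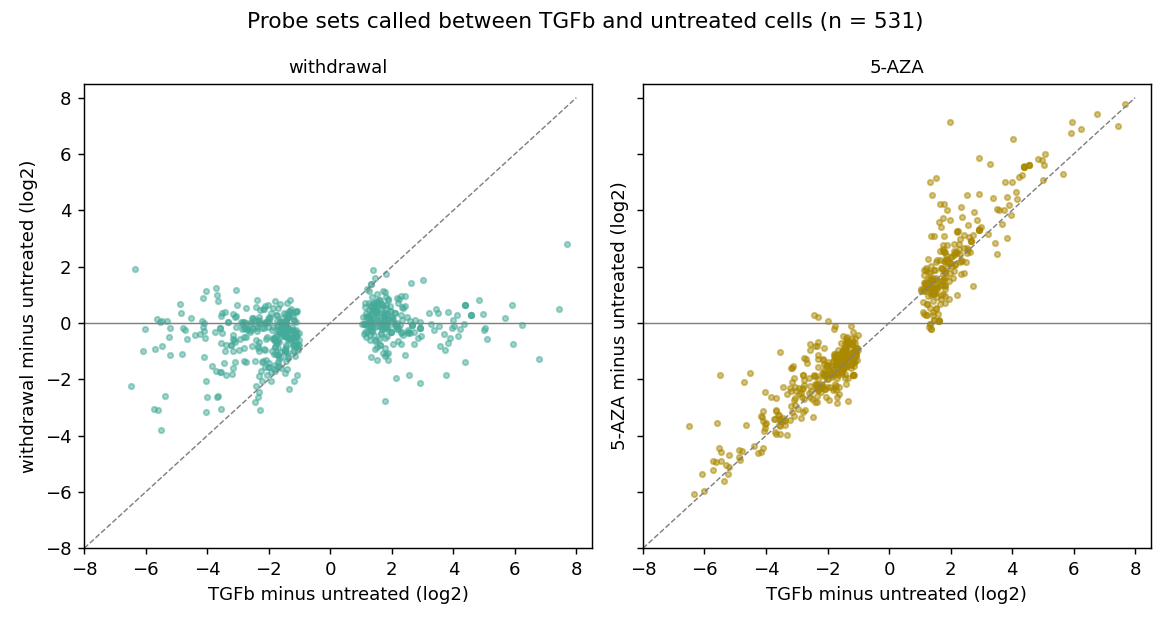
Log2 difference from untreated cells of the withdrawal array (left, vertical axis) and the 5-AZA array (right, vertical axis) against that of the TGFb arrays (horizontal axis), with a point for each of the 531 probe sets called between TGFb and untreated cells. Dashed lines mark equal differences. After withdrawal 81.5% stood nearer to the untreated mean, and in the 5-AZA array 10.9%.

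The 5-AZA array was set against the TGFb arrays to see how cells differed after 72 hours with the drug. The labels do not say whether TGFb was still present during those hours, so these differences can hold the drug, a removal of TGFb or both. In the list of genes normally used in germ cells 9 of 28 were called higher, with the meiotic chromosome protein SYCP3 at 5.47 ± 0.23, adjusted p = 0.00436 and the piRNA pathway gene ASZ1 at 5.78 ± 0.18, adjusted p = 0.00436. Of the mesenchymal list ACTG2 (5.78 ± 0.33), TPM2 (4.64 ± 0.23) and CNN1 (3.29 ± 0.18), which encode an actin and actin-binding proteins, rose, while ACTA2 (2.94 ± 0.63, adjusted p = 0.136) and TAGLN (2.43 ± 0.51, adjusted p = 0.129) were not called. CDCA7, a cell cycle gene tied to chromatin remodelling, fell by 3.34 ± 0.18 (adjusted p = 0.00552). CDH1 differed by 0.24 ± 0.43, adjusted p = 0.873, with a 95% interval of −0.86 to 1.33 that excluded 4.60, the difference seen on withdrawal, and EPCAM by 0.81 ± 0.52, adjusted p = 0.588. ZEB1 (0.09), ZEB2 (0.64), SNAI1 (−0.09), SNAI2 (−0.25), CDH2 (−0.80), VIM (−0.19) and FN1 (0.12) were not called.

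Of 28 germline genes 9 rose and none fell over all genes tested, and 14 rose when adjusted over the list alone (mean log2 difference 1.64, adjusted p = 3.52e-16, and adjusted p = 0.175 with an estimated correlation). Besides SYCP3 and ASZ1 these were GTSF1 (4.69 ± 0.20), SPO11 (4.54 ± 0.19), STK31, DAZL, PIWIL2, SYCP1 and HORMAD1. With the dimmer probe sets dropped only SYCP2 of this list was left, at 0.36 and without a call. Of 22 mesenchymal genes 4 rose and none fell, FSTL1 (4.53 ± 0.24) beside ACTG2, TPM2 and CNN1, with 14 higher and 1 lower over the list alone (mean log2 difference 1.59, adjusted p = 2.75e-13, and adjusted p = 0.175 with an estimated correlation). TGFBI (5.36 ± 0.34), FBN1 (4.02 ± 0.27) and BGN (3.35 ± 0.29) rose among matrix genes and none fell (5 higher over the list alone; mean log2 difference 0.71, adjusted p = 2.20e-05, and adjusted p = 0.198 with an estimated correlation). MMP2 (2.75 ± 0.20) and ADAM19 rose among proteases (7 higher over the list alone; mean log2 difference 0.71, adjusted p = 2.73e-04, and adjusted p = 0.198 with an estimated correlation), and LAMA4 (5.14 ± 0.23) among integrins and laminins (5 higher over the list alone; mean log2 difference 0.54, adjusted p = 0.0013, and adjusted p = 0.306 with an estimated correlation). PRRX1 (3.78 ± 0.17) was the single EMT factor to rise, in both counts (list adjusted p = 0.182).

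All 33 cell cycle genes lay lower in the 5-AZA array, 5 of them called over all genes tested and 30 adjusted over the list alone (mean log2 difference −1.11, adjusted p = 8.07e-26, and adjusted p = 0.175 with an estimated correlation). The replication licensing genes MCM7 (−1.65 ± 0.17), MCM2 (−1.61 ± 0.20) and CDC6 (−2.16 ± 0.24) and the mitotic kinases TTK and PLK1 fell. METTL4, KIF2C, CCDC77 and GINS4 were among the 6 largest decreases, and SFRP4 (6.68 ± 0.29), TKTL1 (6.58 ± 0.25), GALNT5, UCHL1 and TFPI among the 6 largest increases. SLC7A11 fell in the unfolded protein and amino acid response list (1 lower over the list alone; mean log2 difference −0.36, adjusted p = 0.00171, and adjusted p = 0.245 with an estimated correlation).

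Epithelial junction genes had no call over all genes tested and 3 higher over the list alone (mean log2 difference 0.39, adjusted p = 0.00741, and adjusted p = 0.444 with an estimated correlation), and identity genes none in either count (mean 0.12, adjusted p = 0.342). The p53 target list lay higher with no member called in either count (mean log2 difference 0.39, adjusted p = 0.0105, and adjusted p = 0.27 with an estimated correlation). TGFb signalling had 1 gene higher over the list alone (mean log2 difference 0.34, adjusted p = 0.00741, and adjusted p = 0.306 with an estimated correlation). CA2 (3.15 ± 0.20) and SLC4A4 rose in the kidney list (3 higher and 1 lower over the list alone; mean log2 difference 0.31, adjusted p = 0.018, and adjusted p = 0.283 with an estimated correlation). PECAM1 (3.32 ± 0.20), a marker of endothelial cells and platelets, rose among leukocyte, endothelial and neuronal markers (2 higher over the list alone; mean log2 difference 0.37, adjusted p = 0.0385, and adjusted p = 0.444 with an estimated correlation). The kidney and marker lists lost these calls under quantile normalization and under the signal filter, the kidney list also without TGFb replicate 1 (mean 0.27) and the marker list without TGFb replicate 2 (mean 0.35). OAS2 (3.64 ± 0.27) and CXCL10 (2.73 ± 0.35) rose among interferon genes (list adjusted p = 0.162). DNMT1 differed by −0.95 ± 0.18, adjusted p = 0.114, and its list, with 3 lower over the list alone, did not pass (adjusted p = 0.342). The inflammatory, hypoxia, cholesterol and housekeeping lists did not pass either (adjusted p = 0.237, 0.842, 0.988 and 0.341).

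Limma called 337 probe sets between 5-AZA and TGFb, 276 higher and 61 lower. Of the 276, 145 (52.5%) lay among the 25% of probe sets with the lowest untreated and TGFb mean, and 264 were also called higher against untreated cells. The count fell to 137 without either untreated array and to 0 without either TGFb array. It was 110 with the dimmer probe sets dropped, which removed 235 of the 337 calls, and 682 with only named genes tested. CXCL10 was no longer called under quantile normalization, robust moderation or median centring, CCDC77 and MCM2 under quantile normalization, and SLC4A4 with median centring.

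**Figure D3:**
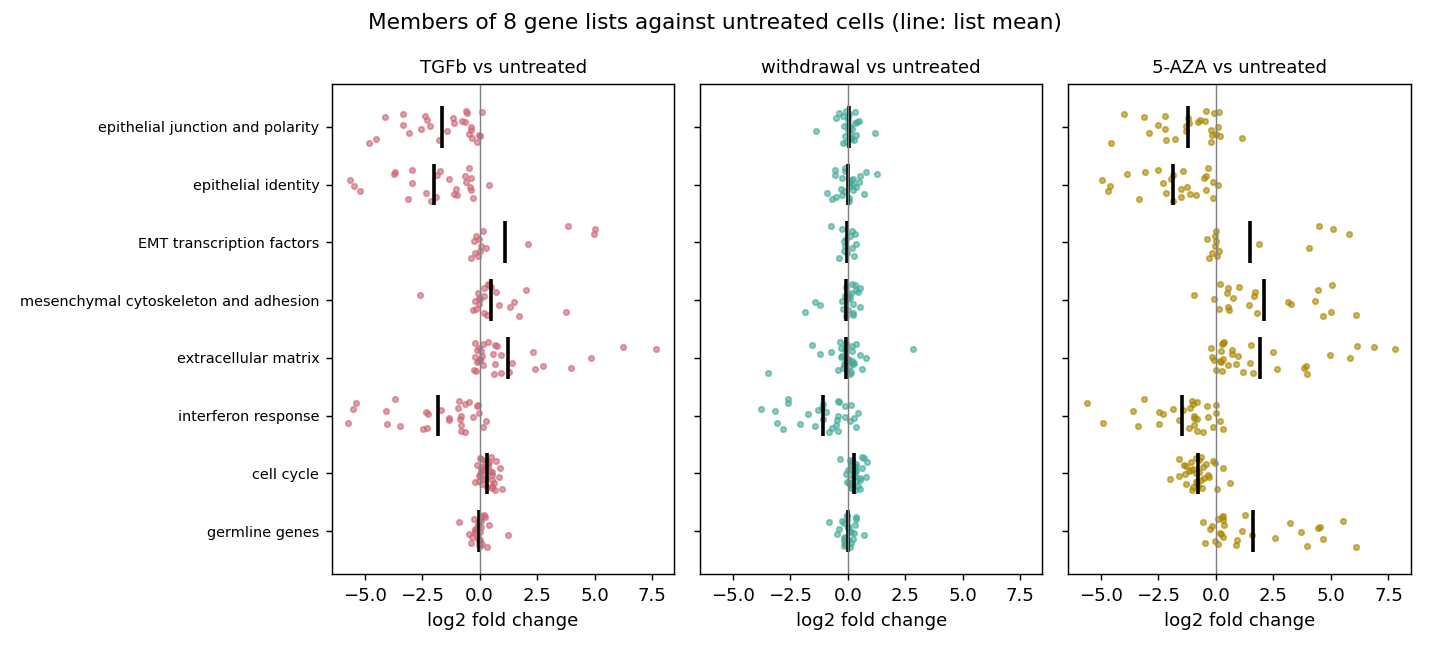
Log2 difference from untreated cells (horizontal axis) of each member of 8 gene lists (vertical axis) in the TGFb arrays, the withdrawal array and the 5-AZA array, with a point per gene and a line at the list mean. Epithelial identity had a mean of −1.99 under TGFb, 0.03 after withdrawal and −1.87 in the 5-AZA array, and germline genes −0.02, −0.00187 and 1.62.

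Against untreated cells CDH1 was lower in the 5-AZA array (−4.55 ± 0.43, adjusted p = 0.0116), and ZEB1 (5.09 ± 0.48) and ZEB2 (4.47 ± 0.53) were higher. The other anchors stood at −2.52 for EPCAM (adjusted p = 0.0795), 1.86 for SNAI2 (adjusted p = 0.067), 0.52 for CDH2, 0.72 for FN1, 0.19 for VIM, −0.03 for SNAI1 and −0.96 for DNMT1, none of them called. LUM (7.78 ± 0.40), LAMA4 (7.13 ± 0.23), KERA, SPARC, NEGR1 and GALNT5 were the largest increases. FGFBP1 (−6.08 ± 0.26), SH3YL1, the interferon genes RSAD2 (−5.61 ± 0.63) and DDX60, RASSF6 and RASEF were the largest decreases. The cyclin-dependent kinase inhibitor CDKN1A rose by 1.79 ± 0.26 (adjusted p = 0.0359), the single call in both counts of the p53 target list (list adjusted p = 0.167).

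Mesenchymal genes counted 11 that rose and none that fell, among them TAGLN (4.43 ± 0.51) and ACTA2 (4.64 ± 0.63), with 17 higher over the list alone (mean log2 difference 2.08, adjusted p = 1.11e-13, and adjusted p = 0.119 with an estimated correlation). Matrix genes counted 11 that rose and none that fell, with 16 higher over the list alone (mean log2 difference 1.93, adjusted p = 1.11e-13, and adjusted p = 0.119 with an estimated correlation), and germline genes 11 and none, with 14 (mean log2 difference 1.62, adjusted p = 1.87e-11, and adjusted p = 0.15 with an estimated correlation). With the dimmer probe sets dropped only SYCP2 of the germline list was left, at −0.54. Of the epithelial identity genes 15 fell and none rose, with 18 lower over the list alone (mean log2 difference −1.87, adjusted p = 2.39e-15, and adjusted p = 0.119 with an estimated correlation). Of the junction genes 7 fell and none rose, with 1 higher and 14 lower over the list alone (mean log2 difference −1.22, adjusted p = 1.74e-08, and adjusted p = 0.252 with an estimated correlation). Of the interferon genes 8 fell and none rose, with 18 lower over the list alone (mean log2 difference −1.49, adjusted p = 3.78e-12, and adjusted p = 0.308 with an estimated correlation). CDC6, CENPF, MKI67, MCM7, TTK and CCNB2 fell among cell cycle genes, with 20 lower over the list alone (mean log2 difference −0.78, adjusted p = 2.14e-11, and adjusted p = 0.15 with an estimated correlation).

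EMT factors counted 4 that rose, with 5 over the list alone (mean log2 difference 1.47, adjusted p = 0.00471, and adjusted p = 0.349 with an estimated correlation), proteases 3, with 10 higher and 1 lower (mean log2 difference 1.04, adjusted p = 2.97e-05, and adjusted p = 0.15 with an estimated correlation), and TGFb signalling genes 4, with 9 higher and 1 lower (mean log2 difference 0.71, adjusted p = 0.00181, and adjusted p = 0.279 with an estimated correlation). The 9 remaining lists besides p53 targets did not pass (adjusted p = 0.051 to 0.884). Limma called 1178 probe sets, 724 higher and 454 lower, and 346 to 435 with an array left out: 346 without untreated replicate 1, 404 without untreated replicate 2 and 435 without either TGFb array. With TGFb against untreated it shared 170 higher and 195 lower calls, where independent lists would share 5.00 and 4.33 and simulated unchanged groups 0.01 on average. The covariance was 0.236 beside a simulated 0.0453, and 0.185 and 0.196 with a different untreated array in each difference. Part of the overlap of calls may come from the shared untreated arrays, and the simulated overlap, from groups without change, cannot size that part.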

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

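The tests restricted to named genes and the counts with identical rows merged were chosen after the data had been seen. Counting each named gene once per comparison, no called difference changed sign where it was refitted: 151 of the 185 under the signal filter, which removed the others, the 51 of TGFb against untreated in the replicate block and in the fit of those arrays alone, and 185 in the remaining settings. Of the 185, 174 were still called under quantile normalization, 177 with robust moderation and 182 with median centring. Dropping probe sets below the median mean signal left 16147 to test and gave 1001 calls for TGFb against untreated, 649 for withdrawal against TGFb and 110 for 5-AZA against TGFb. Every earlier call still tested was kept (440, 245 and 102), and 91, 26 and 235 had been dropped by the filter. Of the germline list 1 of 28 genes was left, SYCP2, at −0.54 against untreated, so that mean changed sign. Under the filter 14.7% of TGFb-called probe sets stood nearer to untreated in the 5-AZA array. Testing 1 probe set per named gene gave 1228, 907, 58 and 682 calls for TGFb against untreated, withdrawal against TGFb, withdrawal against untreated and 5-AZA against TGFb. That setting left out unnamed probe sets and further probe sets of a gene together and refitted the moderation on the rest. The cause was not tested further. Withdrawal against untreated gave 0 calls in every other setting that counted it.

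With each replicated array left out in turn, 1 residual degree of freedom remained and the lone array was assumed to vary like the others. Counts ran from 0 to 129 for TGFb against untreated, 0 to 97 for withdrawal against TGFb, 0 to 137 for 5-AZA against TGFb and 346 to 435 for 5-AZA against untreated. Between 45 and 107 of the 185 named calls passed. The share nearer to untreated ran from 76.0 to 90.7% for withdrawal and 2.86 to 14.4% for 5-AZA, with no value without TGFb replicate 1, where nothing was called. Ranking and measuring on separate arrays gave 74.8, 76.8, 74.2 and 76.8% for withdrawal and 17.9, 25.2, 18.3 and 21.8% for 5-AZA. Selection on the measured arrays is removed there by construction, but the set also differs from the called probe sets.

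Same-numbered untreated and TGFb arrays deviated together only weakly (r = 0.0988 over probe sets, 2 pairs), so they share a number and no pairing was assumed. With the number as a replicate block TGFb against untreated gave 712 calls, CDH2 and P4HA1 were no longer called, and no list call changed. A minimum 2-fold change removed no call, as each exceeded it, and a pseudocount for linear values was not run because the values are logarithms. All 46 list calls ended with an estimated correlation, in a run whose test has 2 degrees of freedom. Without a stated background, how much of the low signal is noise stays unknown.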

Other observations

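The genes in the first 2 paragraphs were chosen after their values were seen, so they stand for themselves and for no wider group. In the 5-AZA array 5 single genes outside the lists that rose against the TGFb arrays had log2 differences of 5.43 for PSMA8, 3.99 for ADAD1, 3.56 for TERB2, 3.27 for MEIOC and 3.03 for TERB1. A list of imprinted genes was written after MEST and PEG3 had been seen, so its count of calls is no evidence for a wider effect. Of its 17 measured genes these 2 rose, MEST (3.66, adjusted p = 0.00559) and PEG3 (2.94, adjusted p = 0.0086), and none fell. The median of the 17 was 0.21, and DLK1 (0.01) and PEG10 (−0.04) stood near 0. Histone probe sets, 55 after merging identical ones, of which 19 carry a symbol of their own, had a median of −1.14 in that array against TGFb, and 8 were called lower. Their median was 0.28 for TGFb against untreated.

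Among single genes outside the lists that fell under TGFb were DDX60 at −5.24, RTP4 at −4.00, PARP9 at −3.57, DTX3L at −3.15 and PARP14 at −3.10. A few genes stood on the far side of the untreated level after withdrawal: NOX4 stood at 2.93 under TGFb and −2.14 after withdrawal against untreated, FYN at 2.13 and −1.97, and FGFBP1 at −6.35 and 1.90. Of the withdrawal differences those of FYN and FGFBP1 passed in the test of named genes alone.

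The tests of TGFb presence and of a transcript shared by LUM, KERA and DCN were written after the result was seen; the others were written before. The interferon list had means of −1.81, −1.49 and −1.09 in the TGFb, 5-AZA and withdrawal arrays against untreated cells. Adjusted over all probe sets, 11, 8 and 0 of its 29 genes were called lower. In the test of named genes alone, its members OAS2 (−3.78), IFI44L (−3.06), CXCL10 (−2.82), USP18 (−2.61) and IFI44 (−2.06) were called lower in withdrawal against untreated. The list's camera calls at the preset correlation ended with an estimated one (adjusted p = 0.299, 0.308 and 0.443), so the list as a group passed under the preset only. The second run, with its 2 degrees of freedom, cannot tell whether correlation between genes undid these calls. For the lower values 2 explanations were tested. A raised signal on 1 untreated array does not account for those of the TGFb arrays, since the list mean under TGFb was −1.55 with one untreated array left out and −2.06 with the other. That check was not run for the 5-AZA and withdrawal arrays. Leaving out 1 array also cannot address a signal raised on both untreated arrays, which may come from the same culture. Whether presence of TGFb was the only cause cannot be told from 1 withdrawal array. The 11 interferon members called lower had a median of −2.58 after withdrawal, where the 26 epithelial members called lower had 0.02. The difference was −2.60 (two-sided permutation over genes, p = 1e-05, the smallest 100000 resamples can give), a test that measures no spread between cultures. Genes are not independent and a single withdrawal array cannot be told apart from a chance low interferon state of that culture.

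In the 5-AZA array 9 of 28 germline genes were called higher than in the TGFb arrays and 19 were not called, and the camera call on the list ended with an estimated correlation (adjusted p = 0.175). A lift of all low signals on that array is argued against by the 25% of probe sets with the lowest signals, whose median difference was 3.23e-04, list members left out. A list that any low-signal genes would match is argued against too: the list median of 0.67 lay at percentile 100 among 10000 random lists matched on mean expression, whose highest median was 0.38. The data are consistent with release of methylation-silenced germline promoters by the drug, a hypothesis resting on 1 array, with the presence of TGFb unstated, without a methylation measurement and without a 5-AZA array of untreated cells.

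LUM, KERA and DCN, which neighbour each other and EPYC (2.33 under TGFb) in the RefSeq table, rose together under TGFb. Whether 1 transcript fed all their probes stays open. LUM exceeded KERA by 2.31 ± 0.46 in withdrawal against untreated, but that is a single array, and KERA read only 3.37 and 3.54 in untreated cells and 3.96 after withdrawal, near the 3.53 below which 25% of probe sets lie by their mean in the untreated and TGFb arrays. The KERA probe set did respond, reading 10.89 under TGFb. On withdrawal it fell by 6.93 ± 0.23, where LUM fell by 4.86 ± 0.40. These falls rest on the same single array, with KERA ending at a low signal, so they do not decide either. Neighbours elsewhere also changed together more often than in shuffled calls. Outside this cluster 13 pairs of unlike names, adjacent among the measured genes, were called in 1 direction. Shuffled calls gave 4.39 on average (one-sided permutation test with 10000 shuffles, p = 8e-04). The same count was 53 against 17.5 for 5-AZA against untreated (permutation p = 1e-04, the smallest these shuffles can give) and 8 against 1.95 for 5-AZA against TGFb (permutation p = 0.0011). For withdrawal against TGFb it was 3 (permutation p = 0.12). The shuffles did not match genes on expression. The rule for unlike names also kept neighbours of related function, such as the junction genes MARVELD2 and OCLN. Regional regulation of the cluster is a possible explanation, and probes of one gene reading into its neighbour were not tested.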
